A study of Homo sapiens with 18 samples.

How the data were processed

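The series holds 18 arrays of chromatin immunoprecipitation followed by hybridisation to a spotted human promoter array (ChIP-chip), 1 array per sample. Per the labels, channel 1 of each array held DNA immunoprecipitated from Daudi cells with an antibody to c-Myc, Max, RNA polymerase II, TAF1 or E2F1, and channel 2 held input DNA. Groups, replicate numbers and array numbers were taken from the labels.

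The deposited values are log2 of the ratio of both channels per spot, already normalized by the authors. The scanner, the dyes, the background correction and the normalization are not given in the sources used here. All values (100%, within 0.01 hundredths) were the log2 of a ratio rounded to 2 decimals, the lowest ratio being 0.01. The deposited median of an array lay between -0.06 and 0. The direction of the ratio is not stated and was read as likely immunoprecipitated over input. On each array between 277 and 778 spots shared 1 exact ratio, between 0.39 and 0.84, as a fill for unmeasured spots would, and these were treated as missing.

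The platform annotation named 5801 probes with 1 gene symbol each, 0 probes with several, and left 2263 unnamed here. Symbols were updated through Entrez identifiers in a RefSeq table of assembly GRCh38.p14, used for names only, which matched 5795 probes and left 6 with their older name. The probes gave 5771 genes, of which 5747 had 1 probe and 24 had several, which were averaged. Among those 24 the probes of a gene differed in their call for 3 genes with c-Myc, 5 with Max, 0 with RNA polymerase II, 4 with TAF1 and 4 with E2F1. The genome build, the coordinates and the sequences of the spotted fragments are not given in the sources used here, so no positions are reported.

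Each array was centred on the median of its named genes, which subtracted 0.014 to 0.15, with no loess or quantile step, since many promoters can be truly enriched. Genes with a value on at least 2 arrays of an antibody were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), on all 18 arrays with a mean per antibody. The spread was thus pooled over antibodies, with a prior of 4.47 degrees of freedom and a prior SD of 0.411. Each antibody's mean was tested against 0, and c-Myc was compared with Max, RNA polymerase II with TAF1 and c-Myc with E2F1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over the genes tested for that antibody or comparison. Calls below 0 were counted as below input, as a measure of background. Errors beside a gene's mean are the SD over arrays, and errors beside a difference are the SE of the fit.

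Overlaps of calls were tested with Fisher's exact test on the genes tested for both antibodies, with 10 pairs adjusted together. A total of 20 gene lists was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists within an antibody or comparison. The lists were canonical c-Myc targets, ribosome biogenesis, ribosomal proteins, translation factors and tRNA synthetases, mitochondrial respiration and import, glycolysis, DNA replication and E2F targets, mitosis and checkpoint, histones, proteasome and ubiquitin, chaperones, RNA splicing, general transcription machinery, the Myc network, and genes of B lymphocytes, T and NK lymphocytes, myeloid and erythroid cells, liver and digestive tissue, neurons and senses, and muscle and skin. Some genes stand on several lists. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

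The design, the gene lists, the main tests, the rule for named genes and a first set of other settings were chosen before the data were examined. The rule took, for each antibody, the 20 (c-Myc) or 10 (others) largest called ratios among genes above 0 on every array and the 2 most negative called genes. It took up to 10 called genes per direction for each comparison, up to 4 members per list with the smallest adjusted p, and 18 genes whatever their values. Of these 18, MAX, POLR2A, NPM1, CDK4, TERT, HSPD1, MCM7 and ALB were not analysed here. Of the 2 most negative genes for c-Myc, 1 is not reported here.

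That set was no centring, centring on the mode or on the tissue-restricted lists, scaling of the arrays to 1 median absolute deviation, each antibody or pair of antibodies alone in the fit, genes measured on all arrays only, a test against a fold of 1.5, an unadjusted p under 0.001, groups of neighbouring array numbers (the leading 2 digits) as a random block, the replicate number as a block, an estimated correlation, and leaving out each array of an antibody. Added after seeing the data were fits without c-Myc replicate 5 and Max replicate 5, with the repeated value kept, on all spots, on single probes, with array weights, on the gene lists with arrays centred on the tissue-restricted lists, without each array of the other antibodies, and with array number groups as a fixed block.

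The steps were tested on simulated data with the spread of the real arrays, but with genes and arrays drawn independently of each other. At a simulated log2 ratio of 1 the fit recovered 89.1% of the changed genes for c-Myc, 83.6% for Max, 67.2% for RNA polymerase II, 67.2% for TAF1 and 59.7% for E2F1. At a ratio of 0.5 it recovered 28.4%, 28.4%, 7.46%, 14.9% and 4.48%. Of simulated differences of 1, 74.6% were recovered for c-Myc versus Max, 42.4% for RNA polymerase II versus TAF1 and 48.4% for c-Myc versus E2F1. Of the calls above input, false calls made up 4.91% for c-Myc and 7.89% for Max. Not counted in these shares were 6 calls below input for c-Myc and 12 for Max, all false. Of the calls in both directions, false calls made up 10.8% for c-Myc versus Max and 1.08% for c-Myc versus E2F1. The other antibodies and the other comparison had 0 false calls. A list shifted by 0.5 was called and 0 of the other lists. In the real data the estimated correlation between genes reached 0.24 within a list, and arrays within an array number group correlated at 0.47. The simulation had neither, so it cannot show how many false calls such correlations give. With independent calls simulated for c-Myc and Max, 5 genes were shared where 4.32 were expected.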

Results

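Chromatin of Daudi cells was immunoprecipitated with antibodies to 5 proteins and hybridised to a human promoter array, with input DNA in the other channel of each array (ChIP-chip). Daudi is an established B-cell line from a Burkitt's lymphoma, a tumour in which a translocation places MYC under the control of an immunoglobulin locus. The antibodies were to c-Myc (5 arrays), to its dimer partner Max (5 arrays), to RNA polymerase II (3 arrays), to TAF1, the largest subunit of the general factor TFIID (3 arrays), and to E2F1, a transcription factor of S-phase genes (2 arrays). The labels number the replicates without saying that they came from separate cultures. P-values of the tests of single genes (limma) thus measure the spread between these 18 arrays, which may be technical. P-values of gene lists and families (camera) and of overlaps (Fisher's exact test) measure a spread over genes instead, not between arrays. The 5801 spots of the array with a gene name gave 5771 genes. No array of an unspecific antibody was used here, and the input channel of each array was its control. The number of arrays limits the precision.

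The ratios are likely those of immunoprecipitated over input DNA, since the labels put the immunoprecipitated DNA first and the values tail upwards. For each antibody the 95th percentile of gene means lay further from 0 than the 5th, at 1.33 against -0.76 (log2) for c-Myc and 0.92 against -0.39 for RNA polymerase II. On single arrays Max replicate 5 was an exception, with a 99th percentile of 2.57 and a 1st percentile of -3.57. Pairs of arrays of the same antibody correlated across genes with a mean r of 0.652 for c-Myc, 0.610 for Max, 0.626 for RNA polymerase II and 0.730 for TAF1, and the 2 E2F1 arrays with r = 0.591. Genes are not independent replicates. Replicate 5 of c-Myc and replicate 5 of Max stood apart, and without them the mean r was 0.772 for c-Myc and 0.686 for Max.

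**Figure D1:**
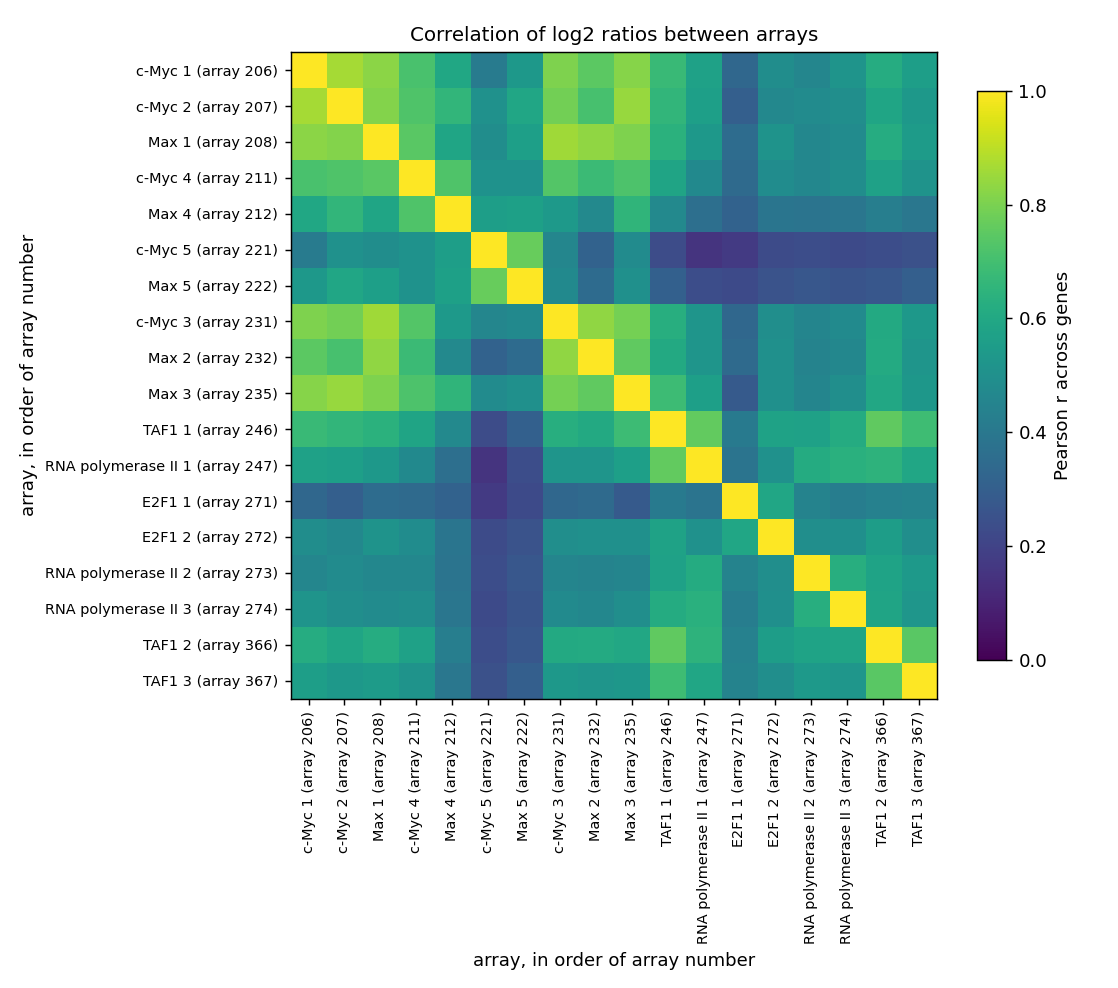
Pearson's r across genes (colour, no unit) between the log2 ratios of each pair of the 18 arrays, with arrays on both axes in order of their array number. c-Myc replicate 5 and Max replicate 5 have mean correlations of 0.472 and 0.496 with the other arrays of their antibody, against 0.571 to 0.795 for the other 8 arrays among themselves.

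Which promoters c-Myc occupied in these cells was the first question. The largest ratio was that of USP1, a deubiquitinase of DNA repair, at a mean log2 ratio of 4.17 ± 0.73 (SD, n = 5). It was followed by TIMM44, part of the motor that imports proteins into mitochondria (3.61 ± 0.50, SD, n = 5), ANAPC10, a subunit of the anaphase-promoting complex (3.49 ± 0.54), and RPS27L, a ribosomal protein paralog (3.29 ± 1.17). ABCE1, a ribosome recycling factor, stood at 3.25 ± 0.80, SND1 at 3.24 ± 0.90, TOP1, DNA topoisomerase I, at 3.21 ± 0.64 and SCO1, a copper chaperone of cytochrome oxidase, at 3.06 ± 0.71. The others of the 20 largest were ZNF134, ATF6, CDC25B, PARP2, RPL18, CCT2, HSPA9, MFNG, IFT25, C9orf43, KDM5A and NUBP1, down to 2.74 ± 0.49. FCGR1A, an Fc receptor of myeloid cells, lay furthest below input among the genes reported (-2.23 ± 0.81, n = 2).

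Of genes long described as c-Myc targets, CAD, an enzyme of pyrimidine synthesis, lay above input at 1.34 ± 0.77 (adjusted p = 0.0011, limma, n = 5). NCL, encoding nucleolin, stood at 0.99 ± 0.39 (adjusted p = 0.0012), LDHA, lactate dehydrogenase, at 1.03 ± 0.74 (0.0032) and EIF4E, the cap-binding protein, at 0.67 ± 0.54 (0.0076). ODC1 (-0.24 ± 0.30), CCND2 (0.11 ± 0.39) and PCNA (0.58 ± 0.55) did not pass the test. Neither did the promoters of MYC (0.03 ± 0.55), E2F1 (0.05 ± 0.65) and TAF1 (-0.17 ± 0.67). These means moved without c-Myc replicate 5, to 0.25 for c-Myc at MYC, -0.24 for c-Myc at E2F1, -0.46 for c-Myc at TAF1 (adjusted p = 0.0196) and 0.81 for c-Myc at PCNA (adjusted p = 0.0233), so that TAF1 and PCNA were then called.

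Of 5669 genes tested, 1201 (21.2%) were c-Myc enriched promoters and 886 lay below input (limma, Benjamini-Hochberg adjusted p under 0.05). The design took the number below input as a measure of background, so part of the 1201 may be background as well. The median log2 ratio of the 1201 was 0.94, 540 lay above 2-fold, and 1006 were above 0 on every array. The balance of above and below depended on the centre of the arrays. It was 1530 to 106 when arrays were centred on their mode, 2056 to 238 when centred on tissue-restricted genes and 1402 to 622 without centring.

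Ribosomal protein genes, chaperones and canonical targets had the highest medians of the 20 gene lists for c-Myc. Of 51 ribosomal protein genes 28 were above input and 2 below (31 above, adjusted over the list alone), with a median of 0.68. RPL18 reached 2.94 ± 0.80, RPL37 2.22 ± 0.55 and RPL19 1.89 ± 0.70 (SD, n = 5). Of 17 chaperone genes 7 were above and 1 below (7 above adjusted over the list alone, median 0.62). Among those above were the chaperonin subunit CCT2 (2.88 ± 0.34) and the mitochondrial HSPA9 (2.88 ± 0.74). The canonical c-Myc targets had 11 of 19 above and 1 below (11 adjusted over the list alone, median 0.60), with NME1 at 1.90 ± 0.69 and HSPE1 at 1.70 ± 0.34. Of 42 proteasome and ubiquitin genes 17 were above and 1 below (17 adjusted over the list alone, median 0.41), with the proteasome subunit PSMA1 at 2.29 ± 0.43 and the activator PSME3 at 2.22 ± 0.63. Of 75 genes of mitochondrial respiration and import 29 were above and 3 below (30 adjusted over the list alone, median 0.40), with the complex I subunit NDUFS1 at 2.17 ± 0.74. Ribosome biogenesis had 13 of 29 above and 1 below (13 adjusted over the list alone, median 0.33), with DDX10 at 2.21 ± 0.54 and NOL7 at 1.43 ± 0.34.

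Set against all other genes, these lists were higher by limma's camera test with a preset correlation. Adjusted p was 3.1e-05 for ribosomal proteins, 0.000243 for chaperones, 0.0185 for canonical targets, 0.000367 for proteasome and ubiquitin, 0.000465 for mitochondrial genes and 0.0391 for ribosome biogenesis. With an estimated correlation between genes none of the 6 was called, with adjusted p = 0.216, 0.114, 0.236, 0.114, 0.320 and 0.304 in the same order. The call of ribosome biogenesis was also lost without c-Myc replicate 3 (ribosome biogenesis and nucleolus, c-Myc, adjusted p = 0.0631), without c-Myc replicate 4 (0.0736), with centring on the mode (0.0576) and with scaled arrays (0.0617). Canonical targets were called with the preset correlation for Max, RNA polymerase II, TAF1 and E2F1 as well (adjusted p = 0.0153, 0.0263, 0.0138 and 0.0113, camera). So were chaperones and proteasome and ubiquitin genes. Canonical targets did not differ between c-Myc and E2F1 (11 of 19 above 0, adjusted p = 0.659, camera). These calls were thus not particular to c-Myc.

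Histone genes were also higher for c-Myc, with 8 of 20 above input (9 adjusted over the list alone), a median of 0.43 and an adjusted p = 0.0185 (adjusted p = 0.216 with an estimated correlation). H2BC4 stood at 2.48 ± 0.56 and H2AZ1 at 1.48 ± 0.55 (SD, n = 5). Of 28 genes of mitosis and checkpoint 6 were above input (4 adjusted over the list alone, median 0.23, adjusted p = 0.0391, and adjusted p = 0.370 with an estimated correlation). ANAPC10, CDC16 (2.07 ± 0.42) and CDC25B (2.97 ± 1.05) led that list, whose call (mitosis and checkpoint, c-Myc) was lost without c-Myc replicate 3, 4 or 5 (adjusted p = 0.0631, 0.0736 and 0.0514) and with centring on the mode (0.0576) or on the tissue-restricted lists (0.0660). Other lists did not pass. DNA replication and E2F targets had 10 of 47 above and 3 below (8 adjusted over the list alone, median 0.20, adjusted p = 0.354). RNA splicing had 9 of 43 above and 5 below (9 adjusted over the list alone, median 0.25, adjusted p = 0.0911), with SNRPD3 at 2.13 ± 0.46. Translation factors and tRNA synthetases had 11 of 41 above and 3 below (11 adjusted over the list alone, median 0.22, adjusted p = 0.273), with EIF4H at 1.58 ± 0.78. General transcription factors had 11 of 39 above and 3 below (11 adjusted over the list alone, median 0.19, adjusted p = 0.170), with YY1 at 1.54 ± 0.40. Glycolysis had 6 of 15 above and 2 below (6 adjusted over the list alone, median 0.19, adjusted p = 0.258). The Myc network had 3 of 12 above and 3 below (4 above adjusted over the list alone, adjusted p = 0.945). Its median was 0.08 while its test pointed down.

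Promoters of genes restricted to other tissues lay below those of other genes for c-Myc. Of 53 liver and digestive genes 18 were below input and 2 above (18 below adjusted over the list alone, median -0.32, adjusted p = 0.00027, and adjusted p = 0.0106 with an estimated correlation). Without replicate 5 of c-Myc and of Max, 30 were below and 0 above, and on c-Myc replicate 5 alone the list median was 0.12. The cytochrome CYP1A2 stood at -0.91 ± 0.42 and CBLIF, gastric intrinsic factor, at -0.95 ± 0.64 (SD, n = 5). Of 32 myeloid and erythroid genes 8 were below and 0 above (8 adjusted over the list alone, median -0.22, adjusted p = 0.0185, and 0.0292 as adjusted p with an estimated correlation, which was 0.234 without replicate 5 of c-Myc and of Max), with FCAR at -0.81 ± 0.37. That call (myeloid and erythroid genes, c-Myc) was lost without c-Myc replicate 3 (adjusted p = 0.0549). The estimated correlation of the myeloid list was -0.0047, below the preset 0.01, so the estimate gave it no stricter test. Of 76 neuronal and sensory genes 17 were below and 10 above (16 below adjusted over the list alone, median -0.21, adjusted p = 0.0185, and adjusted p = 0.216 with an estimated correlation), with the rod transducin gene GNAT1 at -1.16 ± 0.43. Of 50 muscle and skin genes 14 were below and 6 above (14 adjusted over the list alone, median -0.29, adjusted p = 0.0185, and adjusted p = 0.207 with an estimated correlation), with the melanocyte gene MLANA at -1.21 ± 0.49. T and NK lymphocyte genes had 7 of 23 below and 3 above (8 adjusted over the list alone, median -0.34, adjusted p = 0.0610). B lymphocyte genes, the lineage of the cells, had 10 of 35 above and 3 below (11 above adjusted over the list alone, median 0.25, adjusted p = 0.114), with the B-cell kinase BLK at 2.24 ± 0.54 and the antigen receptor chain CD79B at 1.81 ± 0.60. The B lymphocyte median was 0.87 on c-Myc replicate 5 alone, and without that array and Max replicate 5 there were 9 above and 6 below (adjusted p = 0.548). Centring on the mode raised the median gene of c-Myc by 0.28, which turns the sign of the medians of the neuronal and myeloid lists against input but not their place below other genes. Centring on the tissue-restricted lists raised it by 0.28 for c-Myc, 0.26 for Max, 0.12 for RNA polymerase II, 0.23 for TAF1 and 0.16 for E2F1. Of the called lists, that turned the sign of the same 2 medians for c-Myc and for Max, and of both and of muscle and skin genes for TAF1. It also turned liver and muscle genes for RNA polymerase II and myeloid and muscle genes for E2F1. None of these changed its place against other genes. The liver, myeloid, neuronal and muscle lists were called as lower with the preset correlation for Max, RNA polymerase II and TAF1 as well. For E2F1 they were too, except liver genes (adjusted p = 0.0900, camera). With an estimated correlation, liver and neuronal genes kept the call for TAF1 (adjusted p = 0.0037 and 0.0122), while muscle genes lost it (0.0877). The place of these lists below other genes was thus not particular to c-Myc.

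**Figure D2:**
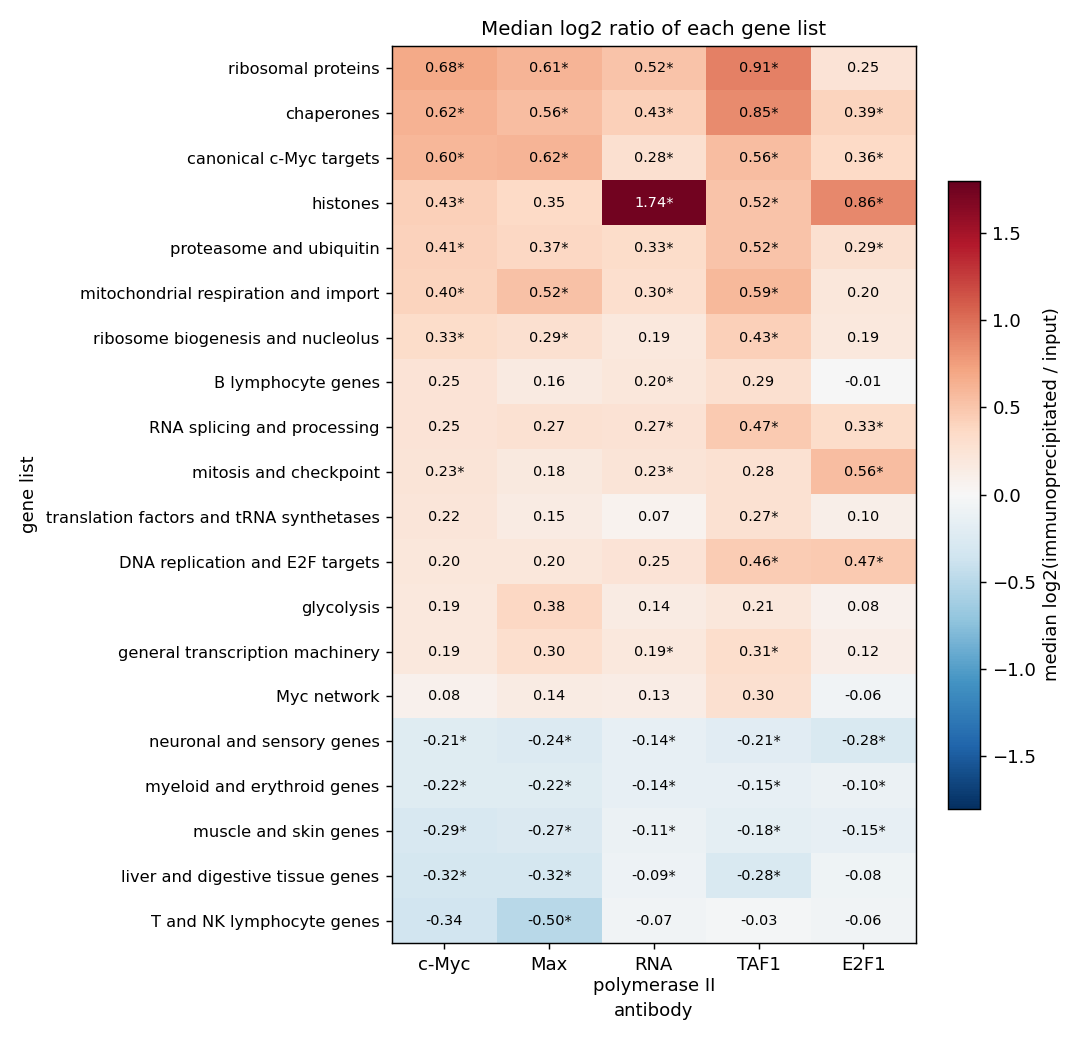
Median over genes of the mean log2(immunoprecipitated / input) ratio (colour and printed value) of each of the 20 gene lists (vertical axis) for each antibody (horizontal axis). Asterisks mark lists that differ from other genes at an adjusted p under 0.05 by camera with a preset correlation. Histones reach 1.74 for RNA polymerase II.

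For Max, the obligate partner of c-Myc, TIMM44 (3.79 ± 0.35, SD, n = 5), ANAPC10 (3.48 ± 0.56), ABCE1 (3.43 ± 0.92) and RPS27L (3.30 ± 0.89) had the largest ratios, followed by MFNG, a glycosyltransferase acting on Notch (3.22 ± 0.61), TOP1, SND1, AKAP10, SCO1 and SCAMP3 (3.07 ± 0.21). CAD stood at 1.16 ± 0.73 (adjusted p = 0.0029), NCL at 0.91 ± 0.45 (0.0020), LDHA at 1.29 ± 0.67 (0.00049) and EIF4E at 0.83 ± 0.40 (0.0015), while MYC was at -0.23 ± 0.43 (adjusted p = 0.33). The most negative were SLC6A14 (-2.54 ± 1.42, n = 2) and ATP5MF (-2.53 ± 2.40, n = 3), and the call of ATP5MF was lost without Max replicate 1, 4 or 5 (Max at ATP5MF, adjusted p = 0.165, 0.164 and 0.0534). Of 75 mitochondrial genes 38 were above input for Max and 4 below (40 above adjusted over the list alone, median 0.52, adjusted p = 2.1e-05, and adjusted p = 0.211 with an estimated correlation). Of 24 T and NK lymphocyte genes 13 were below and 3 above (16 below adjusted over the list alone, median -0.50, adjusted p = 0.0107, and adjusted p = 0.211 with an estimated correlation). Among those below was the cytokine gene IL4 (-1.41 ± 1.55). Max replicate 5 carried much of the mean of IL4, and without that array Max at IL4 was -0.72 (adjusted p = 0.0158). Proteasome and ubiquitin genes had 18 of 42 above and 1 below (19 above adjusted over the list alone, adjusted p = 4.4e-05). Liver and digestive genes had 23 of 53 below and 3 above (23 below adjusted over the list alone, adjusted p = 0.000186). Both calls held with an estimated correlation, with adjusted p of 0.0492 and 0.00994. Without replicate 5 of c-Myc and of Max these were 0.155 and 0.0241, so the proteasome call was then lost. Histones (median 0.35, adjusted p = 0.0602) and mitosis and checkpoint (median 0.18, adjusted p = 0.0781) were not called for Max, but passed without Max replicate 5 (histones, Max, adjusted p = 0.0280, and mitosis and checkpoint, Max, 0.00732). Neither list passed in the direct comparison with c-Myc (adjusted p = 0.704 and 0.795). Of 5711 genes tested, 1308 (22.9%) were Max enriched promoters and 1100 lay below input, against 1963 and 340 when arrays were centred on tissue-restricted genes. Centring on the mode gave 933 above input for Max. It shifted the median gene of Max by -0.03, against 0.28 for c-Myc. As for c-Myc, part of the 1308 may be background.

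c-Myc and Max ratios were close at single promoters. Their gene means correlated with Pearson's r = 0.931 and Spearman's rho = 0.922 across 5660 genes, and 1021 of the 1201 c-Myc promoters (85.0%) were also called for Max, against 6.41% of other promoters. Independent lists would share 277, and the odds ratio was 82.8 (95% interval 67.5 to 101, Fisher's exact test, two-sided, p below the smallest number the computer holds). Of the 180 promoters called for c-Myc and not for Max, 178 had a Max mean above 0, and of the 286 with the reverse pattern 280 had a c-Myc mean above 0. In the direct comparison, c-Myc versus Max, no gene passed (limma, 0 of 5660 genes at an adjusted p under 0.05), and 90 had an unadjusted p under 0.05, where chance gives 283. The differences had an SD of 0.265 and a median 95% interval of ± 0.577 in this fit, which leaves out the array number groups that c-Myc and Max arrays share. With these groups as a random block the interval was ± 0.448, 281 genes had an unadjusted p under 0.05 and 0 were called, and with the groups as a fixed block it was ± 0.483, with 149 genes and 0 calls. Within the 4 groups of neighbouring array numbers that hold both antibodies, r was 0.843, 0.852, 0.726 and 0.768. Over all pairs, c-Myc and Max arrays correlated with a mean r of 0.666, against 0.652 among c-Myc and 0.610 among Max arrays. These groups hold no other antibody. Whether c-Myc lies closer to Max than to the other antibodies through binding or through array series thus cannot be told apart. Of the gene lists, the genes of mitochondrial respiration and import were lower for c-Myc than for Max, with a median difference of -0.13 and 23 of 75 above 0 (adjusted p = 0.00744). Centred on the mode, that median was 0.18, with the list still below other genes. That call was lost with an estimated correlation (adjusted p = 0.931) and without the replicate 5 arrays of both antibodies (adjusted p = 0.310), and in mitochondrial respiration and import, c-Myc versus Max, also without c-Myc replicate 4 (0.111), c-Myc replicate 5 (0.532), Max replicate 3 (0.321) or Max replicate 5 (0.216). Ribosomal protein genes were higher for c-Myc than for Max by a median of 0.13, without passing (adjusted p = 0.0962, camera). Without the replicate 5 arrays of both antibodies that list was called (0.0196), but not with an estimated correlation (0.780). Within the 4 groups its median difference varied in sign, at 0.28, -0.36, 0.25 and -0.06.

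**Figure D3:**
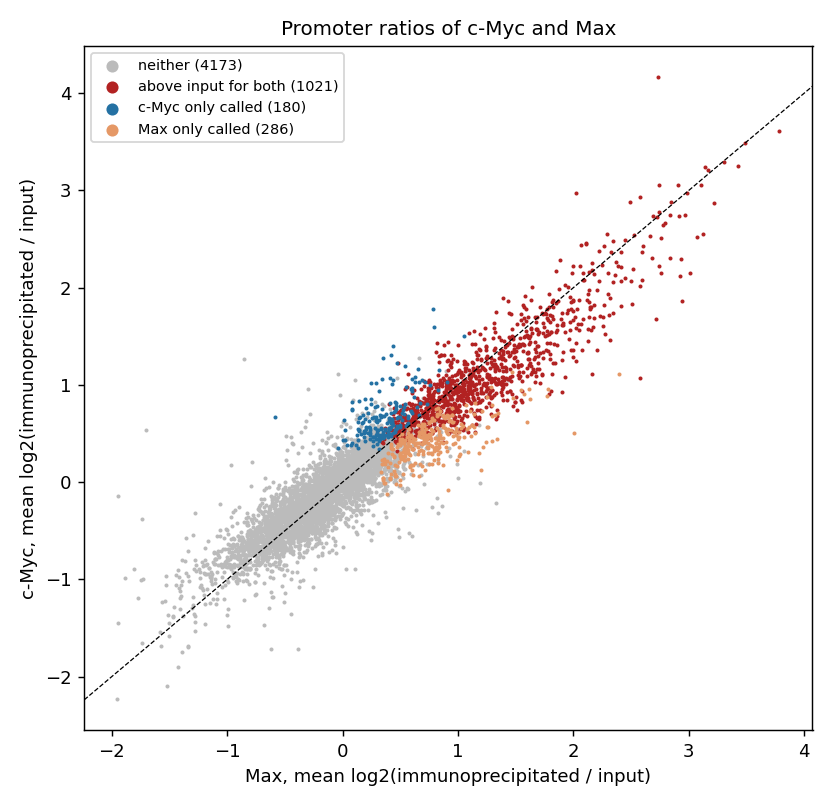
Mean log2(immunoprecipitated / input) ratio of each gene for Max (horizontal axis) and c-Myc (vertical axis), each point a gene, coloured by whether it was above input for both (1021), for c-Myc alone (180), for Max alone (286) or for neither. The dashed line marks equal ratios, and r is 0.931.

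RNA polymerase II marks promoters with engaged or poised polymerase, and its largest ratios were those of replication-dependent histone genes. The 10 largest were all histone genes, led by H2BC4 (3.51 ± 0.40, SD, n = 3), H3C2 (3.45 ± 0.58), H4C2 (3.44 ± 0.55), H2AC11 (3.33 ± 0.30) and H2BC11 (3.27 ± 0.26). Of the 18 histone genes on the list 14 were above input (15 adjusted over the list alone), with a median of 1.74 (adjusted p = 6.7e-44, and adjusted p = 1.5e-20 with an estimated correlation). Of 50 ribosomal protein genes 7 were above (15 adjusted over the list alone, median 0.52, adjusted p = 1.4e-09, and adjusted p = 0.0826 with an estimated correlation), among them RPL10 (2.01 ± 1.08) and RPS20 (1.56 ± 0.15). CD79B (2.10 ± 0.44), the proteasome subunit PSMD14 (1.93 ± 0.75) and TIMM44 (1.76 ± 0.59) were above input as well. MYC stood at 0.85 ± 0.26 without passing (adjusted p = 0.063), and NCL passed at 1.04 ± 0.61 (adjusted p = 0.034). The call of NCL was lost without RNA polymerase II replicate 1 or 3 (RNA polymerase II at NCL, adjusted p = 0.0888 and 0.608).

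In all, 174 of 5520 genes (3.15%) were RNA polymerase II enriched promoters, with a median of 1.41, 144 of them above 2-fold, and 2 lay below input, KCNK1 (-1.70 ± 0.30, n = 2) and MDFI (-1.03 ± 0.62, n = 3). The count depended on single arrays. It was 108 without RNA polymerase II replicate 1 and 70 without replicate 3, where NCL and 18 other named genes lost the call. KCNK1 lost its call without replicate 3 (RNA polymerase II at KCNK1, adjusted p = 0.0809) and MDFI without replicate 1 or 3 (RNA polymerase II at MDFI, adjusted p = 0.333 and 0.0582). Scaling all arrays to 1 spread gave 940 above and 567 below, leaving out replicate 5 of c-Myc and of Max gave 386 above, the mode 91 and array number groups as a random block 74.

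TAF1 was highest at XRN2, an exonuclease of transcription termination (4.17 ± 0.67, SD, n = 3), RPS27L (3.73 ± 0.51), DPM1, of glycosylation (3.17 ± 0.05), and MTF2 (3.02 ± 0.26). SND1, the spliceosome component SNRPD3 (2.96 ± 0.34), RPS6 (2.96 ± 1.10), AP3S2, the proteasome subunit PSMD8 (2.89 ± 0.23) and STK16 followed. Of 50 ribosomal protein genes 26 were above input (34 adjusted over the list alone, median 0.91), among them RPS18 (2.54 ± 0.07) and RPL37 (2.19 ± 0.11), with an adjusted p = 8.2e-17 (adjusted p = 0.00865 with an estimated correlation). Proteasome and ubiquitin genes had 15 of 41 above (20 adjusted over the list alone, median 0.52, adjusted p = 2.9e-07, and adjusted p = 0.00752 with an estimated correlation), with PSMD5 at 2.09 ± 0.10. Chaperones had 8 of 17 above (9 adjusted over the list alone, median 0.85, adjusted p = 2.6e-05, and adjusted p = 0.0428 with an estimated correlation, which was 0.150 without replicate 5 of c-Myc and of Max), with CCT7 at 2.03 ± 0.24. Mitochondrial genes had 29 of 75 above (33 adjusted over the list alone, median 0.59, adjusted p = 5.7e-07), a call lost with an estimated correlation (adjusted p = 0.148). PCNA, the replication clamp, was above input for TAF1 (1.29 ± 0.25, adjusted p = 0.012), a call lost without TAF1 replicate 2 or 3 (TAF1 at PCNA, adjusted p = 0.126 and 0.0516). The most negative were CHRNA3, a nicotinic receptor subunit (-2.73 ± 0.07, n = 2), and DCK (-2.03 ± 1.09, n = 2).

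In all, 638 of 5626 genes (11.3%) were TAF1 enriched promoters, with a median of 1.24, 470 of them above 2-fold, and 46 lay below input. Without TAF1 replicate 1 the count was 318 and without replicate 2 it was 322. Scaling all arrays to 1 spread gave 1114 above and 511 below, leaving out replicate 5 of c-Myc and of Max gave 1066 above and array number groups as a random block 392.

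Polymerase and TAF1, both parts of the initiation machinery, parted at histone genes and, with the preset correlation only, at ribosomal protein genes. At 16 of the 18 histone genes the RNA polymerase II ratio exceeded that of TAF1, with a median difference of 0.83 and list medians of 1.74 and 0.52 (adjusted p = 3.7e-21, and adjusted p = 7.1e-10 with an estimated correlation). Histone genes were above other genes for TAF1 as well, with 7 of 18 above input (adjusted p = 4.0e-05, camera). With an estimated correlation that adjusted p was 0.0122, or 0.0783 without replicate 5 of c-Myc and of Max. H3C2 was higher for polymerase by 2.21 ± 0.37 (SE of the fit, adjusted p = 0.0279) and the linker histone gene H1-4 by 1.86 ± 0.29 (adjusted p = 0.0191). TSPOAP1 was higher by 2.52 ± 0.33 (adjusted p = 0.00254), and AP3S2, of an adaptor complex, was lower, at -2.02 ± 0.36 (adjusted p = 0.0423). Ribosomal protein genes were lower for polymerase, with a median difference of -0.52 and 12 of 50 above 0 (adjusted p = 7.4e-08, and adjusted p = 0.185 with an estimated correlation). So were mitochondrial genes (-0.24, adjusted p = 0.000198, and adjusted p = 0.334 with an estimated correlation), proteasome and ubiquitin genes (-0.25, adjusted p = 0.000781, and adjusted p = 0.185 with an estimated correlation) and translation factors (-0.24, adjusted p = 0.00727, and adjusted p = 0.232 with an estimated correlation). When arrays were scaled to 1 spread, all 4 of these calls were lost. Chaperones (-0.13, adjusted p = 0.0187) and DNA replication and E2F targets (-0.24, adjusted p = 0.0356) were lower as well. Neuronal and sensory genes were higher, by 0.09 (adjusted p = 0.0212). With an estimated correlation the adjusted p was 0.334 for chaperones, 0.584 for DNA replication and 0.258 for neuronal genes. Liver and digestive genes were higher by 0.16, with 37 of 51 above 0 (adjusted p = 0.000781, and adjusted p = 0.0156 with an estimated correlation), a call also lost with scaling, and lost with an estimated correlation without replicate 5 of c-Myc and of Max (0.112).

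The 4 named genes were all that passed in RNA polymerase II versus TAF1 (limma, 3 higher and 1 lower of 5501). The number was 1 or 2 when any 1 of the 6 arrays was left out (1 without TAF1 replicate 1 or 3, 2 without each other), with TSPOAP1 called each time. It was 69 with scaled arrays, 32 without replicate 5 of c-Myc and of Max and 159 with array weights. It was 0 with arrays centred on their mode and 0 with the array number groups as a random or a fixed block. In the only group of neighbouring array numbers with both antibodies, 1 array each, the 2 arrays correlated with r = 0.759 across genes, and the median difference was 0.76 for histone genes (17 of 18 above 0) and -0.40 for ribosomal protein genes.

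**Figure D4:**
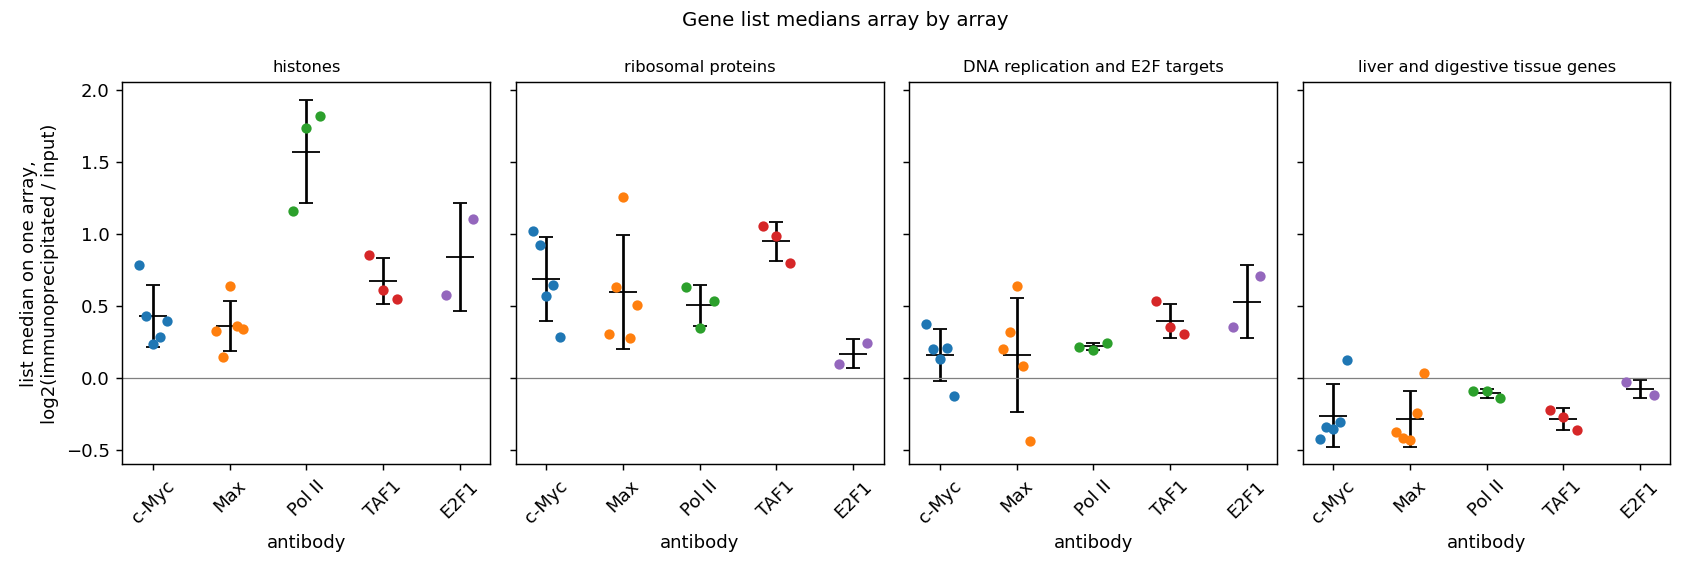
Median log2(immunoprecipitated / input) ratio over the genes of a list on each array (points) for histones, ribosomal proteins, DNA replication and E2F targets, and liver and digestive genes, by antibody (horizontal axis), with lines and bars for the mean ± SD over the arrays of an antibody. The histone medians of the 3 RNA polymerase II arrays, 1.16 to 1.82, lie above those of every other array.

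E2F1 was highest at HNRNPUL1, an RNA-binding protein gene (3.55 ± 0.38, SD, n = 2), the histone gene H4C9 (3.29 ± 0.78), CBX5, encoding the heterochromatin protein HP1 alpha (2.95 ± 0.99), and CCHCR1 (2.91 ± 1.01). The kinetochore gene ITGB3BP (2.79 ± 0.97), KCNH4, CASP8AP2, a factor of histone gene transcription (2.71 ± 1.08), H2AX (2.67 ± 0.64), USP1 and H3C2 (2.54 ± 0.48) followed. DNA replication genes, the group that E2F factors are known for, had 13 of 46 above input (19 adjusted over the list alone, median 0.47, adjusted p = 3.4e-14, and adjusted p = 0.0353 with an estimated correlation). CDC6, a licensing factor of replication origins, stood at 1.93 ± 0.09, the clamp loader subunit RFC3 at 2.15 ± 0.58, the polymerase subunit POLD1 at 1.78 ± 0.44 and CDK1 at 1.79 ± 0.58. Histones had 6 of 18 above (8 adjusted over the list alone, median 0.86, adjusted p = 2.9e-07, and adjusted p = 0.00337 with an estimated correlation). Mitosis genes had 5 of 26 above (7 adjusted over the list alone, median 0.56, adjusted p = 6.0e-06, and adjusted p = 0.0684 with an estimated correlation), with the centromeric histone CENPA at 1.48 ± 0.46. The promoter of E2F1 itself was at 0.34 ± 0.70 (adjusted p = 0.79), and the most negative were FGF8 (-2.50 ± 2.25) and L1CAM (-1.98 ± 2.14), which lost their calls without E2F1 replicate 2 (E2F1 at FGF8, adjusted p = 0.998) and replicate 1 in turn. Of the genes named here as above input, HNRNPUL1, H4C9, CBX5, CCHCR1, CASP8AP2 and CDC6 kept their calls without replicate 2 and the others lost them, with adjusted p of 0.133 for E2F1 at RFC3, 0.182 for E2F1 at POLD1, 0.237 for E2F1 at CDK1 and 0.271 for E2F1 at CENPA.

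In all, 164 of 5277 genes (3.11%) were E2F1 enriched promoters, with a median of 1.58, 149 of them above 2-fold, and 24 lay below input. These calls rest on the spread pooled over all antibodies and on replicate 2. Fitted on the E2F1 arrays alone, 0 genes were called above input, and without replicate 2 the count was 6, with RFC3, POLD1, CDK1, CENPA and 32 other named genes losing the call. Scaling all arrays to 1 spread gave 590 above and 365 below, leaving out replicate 5 of c-Myc and of Max gave 393 above, the mode 49 and array number groups as a random block 39.

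c-Myc and E2F1, both sequence-specific factors, differed at named genes in each direction. Higher for c-Myc were ATF6, of the endoplasmic reticulum stress response (difference 3.68 ± 0.64, SE of the fit), L1CAM (3.24 ± 0.61), RPS27L (3.17 ± 0.67), MFNG (2.82 ± 0.41) and NUBP1, of iron-sulfur assembly (2.65 ± 0.41), then TEKT2, LTA4H, SCAMP3, ANAPC10 and STAT6. Lower for c-Myc were H4C9 (-2.48 ± 0.33), CASP8AP2 (-2.38 ± 0.34), HNRNPK (-2.27 ± 0.51), H4C3 (-2.24 ± 0.51), RFC3 (-1.96 ± 0.33) and the replication kinase CDC7 (-1.89 ± 0.33), with H3C2, CCHCR1, CBX5 and SRSF2. DNA replication and E2F targets were lower for c-Myc as a group, with a median difference of -0.56 and 8 of 46 above 0 (adjusted p = 6.6e-07, and adjusted p = 0.517 with an estimated correlation). Ribosomal protein genes were higher by 0.54 (37 of 50 above 0, adjusted p = 0.00319, and adjusted p = 0.630 with an estimated correlation), a call (ribosomal proteins, c-Myc versus E2F1) lost with scaled arrays (0.136) and without E2F1 replicate 1 (0.0875). Mitochondrial genes were higher by 0.25 (adjusted p = 0.0361, and adjusted p = 0.630 with an estimated correlation) and liver and digestive genes lower at -0.22 (adjusted p = 0.0361, and adjusted p = 0.446 with an estimated correlation). The list mitochondrial respiration and import, c-Myc versus E2F1, lost its call without c-Myc replicate 1 (0.128), c-Myc replicate 2 (0.0961) or E2F1 replicate 1 (0.208). The list liver and digestive tissue genes, c-Myc versus E2F1, lost its call without c-Myc replicate 1, 2, 3 or 4 (0.128, 0.0548, 0.0686 and 0.0662) or E2F1 replicate 1 (0.262). Centred on the mode, its median was 0.09 and it was not called (0.0965).

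In c-Myc versus E2F1, 48 of 5273 genes were higher for c-Myc and 27 lower (limma, 75 calls). The number was 43 without c-Myc replicate 2, 43 without E2F1 replicate 1 and 10 without E2F1 replicate 2, where MFNG, L1CAM and NUBP1 alone of the named genes kept their calls. MFNG kept its call without each single array. The difference in c-Myc versus E2F1, L1CAM, rested on E2F1 replicate 1 and was 1.73 without it, where its call was lost (adjusted p = 0.245). With arrays centred on their mode 17 were higher and 2 lower, and with arrays scaled to 1 spread 158 and 271. No group of neighbouring array numbers holds both antibodies, and with these groups as a random block 9 genes passed.

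Polymerase, TAF1 and E2F1 were found more often at c-Myc promoters than at others. Of 1158 c-Myc promoters tested for both, 139 (12%) were also called for RNA polymerase II, against 0.806% of other promoters (odds ratio 16.8, 95% interval 11.4 to 25.2, Fisher's exact test, two-sided, adjusted p = 6.5e-64 over 10 pairs). Independent lists would share 36.6. TAF1 was called at 438 c-Myc promoters (36.7%, against 4.52% of others, odds ratio 12.3) and E2F1 at 117 (10.6%, against 1.10%, odds ratio 10.7). Without replicate 5 of c-Myc and of Max the odds ratios were 8.98 for RNA polymerase II, 11.6 for TAF1 and 5.17 for E2F1. The shared calls were then 275 of 1379 c-Myc promoters for RNA polymerase II, 717 of 1398 for TAF1 and 236 of 1341 for E2F1. The shares thus depend on how many promoters are called, and do not measure how many c-Myc promoters carry polymerase. The median RNA polymerase II ratio was 0.39 at c-Myc promoters and -0.05 at other genes, and the median TAF1 ratio 0.64 and -0.09. Of the 174 polymerase promoters 146 (83.9%) were called for TAF1 (odds ratio 51.5), and all 5 proteins were called at 49 of 5264 genes, among them CD79B, HSPE1, PSMA1, TIMM44, CDC25B and H2BC4. No protein was called at 3732 genes. Promoters are not independent replicates, and whether arrays shared an input sample is not given in the sources used here, so part of these overlaps may come from input DNA or from spots that 2 antibodies share.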

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

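All tests of the explanations in this part were chosen after the result was seen.

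For c-Myc the mean correlation of replicate 5 with the other c-Myc arrays was 0.472, against 0.671 to 0.721 for the others. Of named genes, the E2F1 promoter stood at 1.19 on c-Myc replicate 5, with -0.43 to -0.10 on the others, and PCNA at -0.35 there, with 0.62 to 0.99 on the others. On Max replicate 5 the MYC promoter was at -0.99, with -0.09 to 0.03 on the others. TOP1 was at 2.09 on c-Myc replicate 3, with 3.38 to 3.70 on the others, and LDHA at 2.46 on Max replicate 3, with 0.84 to 1.17 on the others. These 6 were the sets of 5 arrays, of 55 checked, in which a single array lay far from the rest by Dixon's ratio, which chance gives in about 1 in 20 sets (2.75 of 55).

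c-Myc replicate 5 and Max replicate 5 stood apart together. A wrong label with an RNA polymerase II, TAF1 or E2F1 sample is argued against, since both arrays correlated better with c-Myc or Max than with any of the others, by at least 0.265 in r. A scale factor as the only cause is argued against as well. It leaves correlations as they are, and the mean r of both arrays (0.472 and 0.496) lay under the 0.571 to 0.795 of the other 8. Both arrays did differ in scale too, with a median absolute deviation over genes of 1.39 and 1.19, against 0.43 to 0.78 for the other 8. Deviations of both arrays from the means of their antibodies correlated with r = 0.624. However, pairs from different array number groups also reached 0.491 (c-Myc replicate 3 with Max replicate 1) and 0.402 (c-Myc replicate 1 with Max replicate 3). A pair within a group, replicate 3 of both, gave 0.030. The correlation of deviations thus cannot show a shared array batch. The array numbers of replicate 5 of c-Myc and of Max are neighbours, and a batch stays open. A swap between these 2 stays open, since replicate 5 of c-Myc correlated with c-Myc at 0.508 and with Max at 0.531, and replicate 5 of Max at 0.578 and 0.567, and no biological explanation was tested.

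Spots without a gene name, which enter none of the comparisons, lay on both sides of input. Counted with all spots tested alone, those above were 189 of 2066 for c-Myc (9.15%, against 23.5% of named spots), 228 of 2071 for Max (11%), 12 for RNA polymerase II (0.609%), 69 for TAF1 (3.41%) and 11 for E2F1 (0.589%). Those below were 439 for c-Myc, 530 for Max, 0 for RNA polymerase II, 19 for TAF1 and 3 for E2F1.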

How the results depend on the processing

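The fits without c-Myc replicate 5 and Max replicate 5, with the repeated value kept, on all spots, on single probes, with array weights, with a fixed array block, on the gene lists with tissue-restricted centring, and without arrays of other antibodies were chosen after the results were seen. Among the genes named, no called mean or difference changed sign under any alternative run. Some medians of called lists did. Centred on the mode, the median was 0.06 for myeloid and erythroid genes, c-Myc, 0.06 for neuronal and sensory genes, c-Myc, 0.18 for mitochondrial respiration and import, c-Myc versus Max, and 0.09 for liver and digestive tissue genes, c-Myc versus E2F1. Centred on the tissue-restricted lists, the medians of myeloid and erythroid genes, c-Myc (0.06), neuronal and sensory genes, c-Myc (0.06), myeloid and erythroid genes, Max (0.04), neuronal and sensory genes, Max (0.01), liver and digestive tissue genes, RNA polymerase II (0.03), muscle and skin genes, RNA polymerase II (0.01), myeloid and erythroid genes, TAF1 (0.07), neuronal and sensory genes, TAF1 (0.02), muscle and skin genes, TAF1 (0.05), myeloid and erythroid genes, E2F1 (0.06), muscle and skin genes, E2F1 (0.01) and neuronal and sensory genes, RNA polymerase II versus TAF1 (-0.02) turned. For chaperones, RNA polymerase II versus TAF1, it was 0.07 with scaled arrays and 0.08 without TAF1 replicate 1. In c-Myc versus E2F1 the balance turned with scaled arrays, from 48 higher and 27 lower to 158 and 271. Where a cause is not named below, the cause was not tested.

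For c-Myc enriched promoters (1201) and Max enriched promoters (1308), centring on the tissue-restricted lists gave 2056 and 1963, a test against a fold of 1.5 gave 256 and 389, and an unadjusted p under 0.001 gave 684 and 784. All other settings kept both counts within 1.5 times, at 910 to 1358 and 1046 to 1523 when single arrays were left out.

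For RNA polymerase II enriched promoters (174), TAF1 enriched promoters (638) and E2F1 enriched promoters (164), in this order, scaled arrays gave 940, 1114 and 590, a fold of 1.5 gave 53, 151 and 27, the random array block 74, 392 and 39, array weights 714, 1228 and 341, and leaving out c-Myc replicate 5 and Max replicate 5 gave 386, 1066 and 393. Centring on the mode gave 91 for RNA polymerase II and 49 for E2F1, centring on the tissue-restricted lists 284 for RNA polymerase II and 1046 for TAF1, and an unadjusted p under 0.001 gave 408 for TAF1. E2F1 arrays alone gave 0. Leaving out single arrays gave 70 to 233, 318 to 801 and 6 to 209. Leaving out an E2F1 array leaves 1, which is then assumed to vary like those of other antibodies. c-Myc replicate 5 and Max replicate 5 enter the pooled spread, but not the means of RNA polymerase II, TAF1 and E2F1. The higher counts without these arrays thus came from a smaller pooled spread.

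For c-Myc versus Max the count was 0 under each setting but array weights, which gave 2, and 0 to 0 without single arrays. For RNA polymerase II versus TAF1 (4) it was 0 with the mode, 0 with the random and 0 with the fixed array block, 1 with the 2 antibodies alone, 69 scaled, 32 without both replicate 5 arrays, 2 on all spots, 159 with array weights, and 1 to 2 without single arrays. For c-Myc versus E2F1 (75) it was 19 with the mode, 429 scaled, 9 with the random block, 43 with the 2 antibodies alone, 350 without both replicate 5 arrays, 144 with the repeated value kept, 310 with array weights, and 10 to 101 without single arrays.

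Replicate numbers did not pair all arrays. Deviations of same-numbered arrays correlated with r = 0.201, 0.111, 0.030, 0.391 and 0.624 for c-Myc and Max, 0.180, 0.032 and -0.083 for RNA polymerase II and TAF1, and -0.197 and 0.051 for c-Myc and E2F1, and not every array correlated best with its own number. c-Myc replicates 4 and 5 did correlate best with the Max array of their number, which is also a neighbour by array number. The E2F1 arrays deviate from their mean as mirror images, so the signs of their values are forced to be opposite. With the replicate block, c-Myc versus Max gave 0 calls, RNA polymerase II versus TAF1 0 and c-Myc versus E2F1 0.

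The odds ratio for Overlap of c-Myc and Max calls was 42.8 to 92.5 without single arrays and 63.9 to 291 under other settings, and for RNA polymerase II calls among c-Myc calls 10.7 to 18.1 and 8.13 to 20.9. Of the 12 gene lists called for c-Myc (Gene lists), 2 passed with an estimated correlation, which for the myeloid list lay below the preset. Without single arrays 9 to 12 passed. Over all alternatives, 568 values of named genes lost their call and 291 gained one, while 6447 stayed as they were, called or not called. Of the named differences, which were all called, 135 lost their call while 248 kept it. For lists, 140 lost a call, 50 gained one and 2010 stayed as they were, called or not called. With the fold of 1.5 a total of 165 named values lost the call, with the antibody's own arrays alone 76, and with the mode 65. The number of arrays limits the precision.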

Other observations

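All tests in this part except the other splits of the arrays were chosen after the result was seen, on families read from gene symbols or seen in the report.

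Within the histone genes, H2A and H2B promoters, H2A variants included, lay above those of H1, H3 and H4 for c-Myc. The 24 H2A and H2B genes had a mean log2 ratio of 1.19 ± 0.65 (SD over genes, 18 above input), against 0.16 ± 0.58 for 30 other histone genes (6 above), with a permutation p adjusted over 5 antibodies of 2.5e-05, from the smallest p that 100000 permutations can give (1e-05). For Max the means were 1.26 and 0.17 (adjusted p = 2.5e-05), for TAF1 1.62 and 0.58 (3.3e-05), for E2F1 1.31 and 0.72 (0.013) and for RNA polymerase II 2.48 and 1.40 (7e-04, 21 of 24 and 17 of 28 above input). Many H2A and H2B genes lie as divergent pairs, so that spots of neighbours may hold the same promoter, and the genes are then not independent. The sharing of sequence was not tested.

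Of the 49 genes above input for all 5 antibodies, 16 were histone genes, of 50 tested for all (odds ratio 73.4, 95% interval 34.4 to 153, Fisher's exact test, p = 8.3e-22). Among 16 families read from gene symbols, histones were higher for c-Myc by camera (24 of 54 above input and 3 below, median 0.49, adjusted p = 3.1e-05). So were subunits of the RNA polymerases (8 of 16 above input and 2 below, median 0.63, adjusted p = 0.0174) and nucleoporins (3 of 7 above, median 0.54, adjusted p = 0.0210). Each of these families, histones included, had an adjusted p = 0.177 with an estimated correlation. Lower were interleukins and their receptors (11 of 49 below and 3 above, median -0.39, adjusted p = 0.0105, and adjusted p = 0.372 with an estimated correlation) and cytochrome P450 genes (9 of 29 below and 0 above, median -0.17, adjusted p = 0.0174, and adjusted p = 0.177 with an estimated correlation). With arrays centred on the mode, which raised the median gene of c-Myc by 0.28, the median of the cytochrome P450 genes would turn above input.

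RNA polymerase II lay above TAF1 at histone promoters, by a median of 0.83. A wider scale of the polymerase arrays is argued against, since the 136 other promoters called for polymerase had a median difference of -0.13 (95% interval -0.22 to -0.05). An array batch cannot be told apart, since a single group of array numbers holds both antibodies, with 1 array each (0.762), although against E2F1, with 2 arrays each in another group, the polymerase median was also higher, by 0.97 at 16 of 18 genes above 0. Fragments shared between histone genes stay open too, since the spotted sequences were not used here, and the difference had an SD of 0.772 over the 18 genes. The 10 splits of the 6 arrays are too few for a share under 0.05 (1 of 10 as large, real value 0.83, highest other 0.40), and higher polymerase per TAF1 at histone genes may be biological, which was not tested.

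For c-Myc 886 and for Max 1100 promoters lay below input, with 2, 46 and 24 for RNA polymerase II, TAF1 and E2F1, which have fewer arrays and reach 567, 511 and 365 with scaled arrays (RNA polymerase II enriched promoters, TAF1 enriched promoters and E2F1 enriched promoters). Centred on tissue-restricted genes, which lie below others, 238 and 340 were left, but that centre lowers the number whatever the cause, so whether the choice of centre accounts for them cannot be told apart. Whether spots biased alike with every antibody add to them cannot be told apart, since these genes had a median of -0.62 for c-Myc and -0.58 for Max, but -0.23 for TAF1, -0.14 for RNA polymerase II and -0.14 for E2F1. No biological explanation was tested.

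For c-Myc versus Max the real count of 0 calls leaves the other splits nothing to test, since all 100 splits drawn of the 10 arrays must reach it. The highest other split gave 24, which points to a structure of the samples. It parted the array number groups from each other, with c-Myc replicate 2 alone on the other side from its group, and with these groups as a fixed block c-Myc versus Max gave 0 calls. For RNA polymerase II versus TAF1 the 10 splits are too few for a share under 0.05 (1 of 10 as large, real count 4, highest other 0).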
